A study of Drosophila melanogaster with 3 samples.

How the data were processed

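Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed, per the labels, on whole prepupae of Drosophila melanogaster of mixed sex. The animals carried a transgene that stably expresses Plzf, the product of CG6792, with green fluorescent protein fused to its C terminus, per the labels. The immunoprecipitation used an antibody against GFP according to the description in the labels, while the antibody field of the labels names CG6792. Chromatin was sonicated to a size range of 200 to 800, per the labels. The series holds 1 group of 3 biological replicates, numbered 1 to 3 in the labels, and no second condition, so no contrast between groups was possible. The comparisons were therefore between replicates, between selected and unselected regions, and between summits and their flanks.

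The deposited lists are in the narrowPeak format, per the file headers of the accompanying notes, and exist for the dm3 and dm6 assemblies. For each replicate and for the 3 replicates pooled, the authors deposited up to 30000 regions, peaks and background together, as input to the irreproducible discovery rate (IDR) procedure, which ranks regions by their agreement between replicates. A further list per assembly holds the optimal IDR-thresholded peaks, per the file headers. A control library entered the calling of the regions, per the file headers. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here.

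The signal of each region is the peak height that the authors' caller gave, on the scale of its own list, so it was used only to rank, filter and describe regions within a list. The deposited −log10 q-value reaches a ceiling shared by many regions (10260 of 30000 in replicate 2, and 3476 and 3343 in replicates 1 and 3) and was not used for ranking. The summit is the deposited offset from the region start. The IDR list on dm6 was tested against the pooled list: all 7096 IDR peaks were the 7096 pooled regions of highest signal, down to a signal of 79.6. The number of reads per library is unknown from these lists, so no value here carries a sequencing depth. Confidence intervals of 95% on shares of regions are Wilson intervals and cover the counting of regions only. Regions and genes are not independent replicates, and every p-value is across regions or genes, not across animals.

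All coordinates are dm6, counted from 1. Genes and transcription start sites (TSSs) came from Ensembl release 115, and sequence from the RefSeq genome of the same assembly. Annotated transposable elements were left out. No dm3 coordinate was used or converted, and the dm3 lists entered counts only. The list of 30000 regions of replicate 2 holds 6 on the mitochondrial genome, which were left out of location and sequence tests.

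Replicate support counted IDR peaks with a reciprocal overlap of 50% among the 7096 regions of highest signal of each replicate, set beside 100 random shifts of the peaks within chromosomes. Each summit was placed within 500 bp of a TSS (called promoter here), else in a 5′ UTR, coding exon, 3′ UTR, other exon, intron or between genes. The control for location, chromosomes and genes was the 21147 pooled regions that did not overlap an IDR peak, or, for genes, the genes with any pooled region at a TSS, because these could have been selected. Tests were two-sided Fisher's exact tests with Woolf intervals of the odds ratio, and 0.5 was added to each cell where 1 was 0. The trend of the promoter share over signal quartiles used 100000 permutations.

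The 33 gene lists and the 30 sequence motifs were fixed before the data were examined, as were the tests and the alternatives unless stated. Lists with at least 5 genes in the control set were tested. Motifs and 7-mers were searched on both strands within 50 bp of the summit and in windows of the same width centred 300 bp away on each side, with an exact McNemar test of the summit window against the flank at higher coordinates. Log2 ratios of peak numbers carry a pseudocount of 1 peak. Flank shares and log2 ratios against the flanks use the mean of both sides, while the test used 1 side. All families of tests were adjusted by the Benjamini-Hochberg method at 0.05. For a control of equal base composition, each summit window was matched, in bins of 2 percentage points of GC content, to a summit window of another pooled region.

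The genes named in the report followed a rule. They are the protein-coding genes with the nearest TSS within 500 bp of the strongest IDR peaks held by all 3 replicates, up to 25 genes. For each gene list past the threshold, the 4 members of highest signal and up to 2 members without an IDR peak were added. The 5 strongest such peaks with no TSS within 500 bp, Plzf itself and white (w), a usual transgene marker, complete the set.

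The gene list, motif and 7-mer tests were tested on simulated data. For the gene list test, 20 of 20 simulated lists of 77 genes with a raised share of peaks were recovered, and 0 of 200 random lists passed. This is the size of the cytosolic ribosomal protein list. The other lists tested had 6 to 41 genes, and recovery at those sizes was not simulated. For the motif test, a word placed in 10% of 2000 random windows was found in 10.3% of them. Of the other motifs 0 of 26 passed, with the BEAF-32 box, GATA and the homeodomain core left out of the count. Here and for 7-mers, simulated summits and flanks had the same base composition. The simulation therefore does not cover false calls that arise from the GC difference between real summits and flanks. For the 7-mer test, the placed 7-mer ranked 1 of 8192, and 15 7-mers were called higher, 2 of them placed. The alternatives were other overlap rules, TSS windows, controls, word lengths, numbers of peaks and the omission of each replicate in turn. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.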

Results

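The data are region lists from ChIP-seq of GFP-tagged Plzf, a zinc finger protein, in whole prepupae, the stage of Drosophila at the onset of metamorphosis. There were 3 biological replicates of 1 group. Each replicate had a list of 30000 regions on dm6, and the authors selected 7096 peaks by IDR from the pooled list of 30000. The IDR peaks had a median width of 440 bp, formed 6631 separate intervals and covered 2605677 bp, or 1.95% of the chromosome arms. Peak signal, the height given by the authors' caller, ranged from 79.6 to 3444 with a median of 145.0.

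To measure how far the replicates held the same binding sites, the IDR peaks were looked up among the 7096 strongest regions of each replicate. The strongest peak, in an intron of ush, and the peaks at the promoters of Ugalt and CG14100 were present in all 3 replicates. Such peaks were named only if all 3 replicates held them, so this does not measure agreement. Of the 7096 IDR peaks, 73.2% were found in replicate 1, 77.7% in replicate 2 and 72.2% in replicate 3, a mean of 74.35% ± 2.94 (SD, n = 3). All 3 replicates held 3753 peaks (52.9%, 95% interval 51.7 to 54.1), against a mean of 54.0 and at most 74 peaks after 100 random shifts. The pooled list was made from the same 3 replicates, so an overlap above that of random shifts was fixed by the design and does not measure their agreement. Replicate 2 had the highest share here but the lowest overlaps with the other replicates. The weight of each replicate in the pooled list is not known, so these shares do not rank the replicates by agreement. At least 2 replicates held 5590 peaks (78.8%), and 611 (8.61%) were found in none. By signal, 65.7% of the strongest quartile and 15.1% of the weakest quartile were in all 3 replicates under the 50% reciprocal rule. With an overlap of 1 bp instead, 99.6% of the strongest and 19.8% of the weakest quartile were. The reciprocal rule therefore missed many strong peaks that overlapped a region in each replicate. When all regions of each replicate were searched with the reciprocal rule, the weakest quartile reached 92.4% and the strongest 66.1%, so the order by signal was the opposite. With summits within 100 bp in all regions, the weakest quartile reached 74.3% and the strongest 98.03%.

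**Figure D1:**
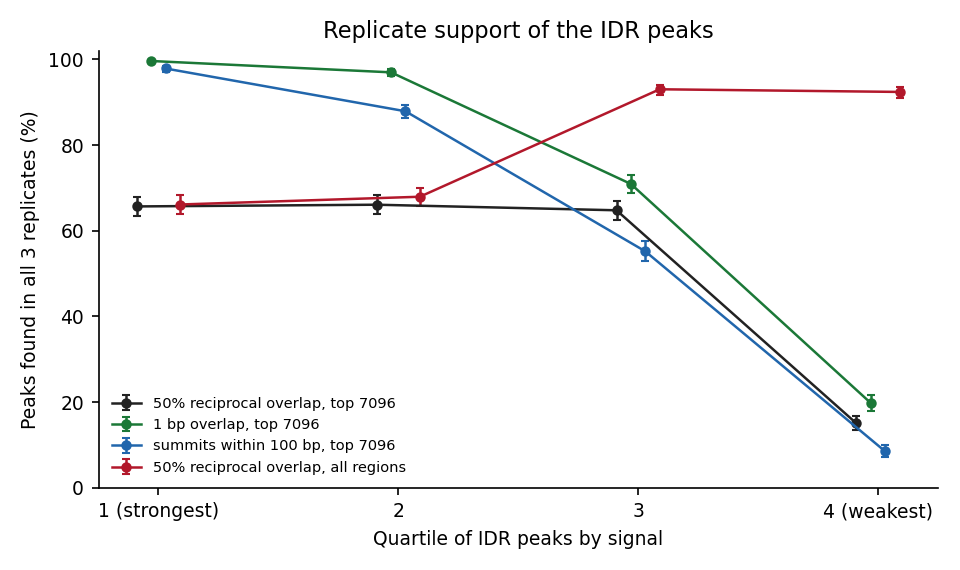
Share of IDR peaks found in all 3 replicates (y axis, percent, with 95% Wilson intervals) by quartile of peak signal (x axis, strongest first), for 4 rules of overlap. In the strongest quartile the 1 bp rule gave 99.6% and the reciprocal rule 65.7%, and in the weakest quartile only the search of all regions exceeded 90%.

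Replicates 1 and 3 shared more of their strongest regions with each other than either did with replicate 2. The mean overlap of the 7096 strongest regions was 76.7% for replicates 1 and 3, 68.7% for 1 and 2, and 68.0% for 2 and 3. Over the 5667 IDR peaks matched in the full lists of all 3 replicates, Spearman's rho of the signal was 0.751, 0.681 and 0.677 for the same pairs. This matched set held 66.1% of the strongest quartile of IDR peaks, then 67.9%, 93.0% and 92.4%, so stronger peaks were under-represented. These correlations are across regions, which are not independent, and no test of the difference between pairs was made.

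To describe where Plzf-eGFP bound, each summit was placed on the gene annotation. Promoters held 2635 of 7096 IDR summits (37.1%, interval 36.0 to 38.3), against 24.3% of the other pooled regions and 13.55% of the bases of the arms. The odds ratio was 1.84 (1.74 to 1.95; Fisher's exact p = 2.76e-94), and the replicates' own strongest regions gave 38.25% ± 0.804 (SD, n = 3). Introns held 42.8% of the IDR summits and 46.4% of the other regions, and intergenic sequence held 17.6% and 23.6%. Coding exons were nearly empty, with 13 summits (0.183%) against 1.77% of the other regions and an odds ratio of 0.102 (0.0586 to 0.177; Fisher's exact p = 9.47e-32). The 5′ UTRs (0.437% against 1.08%) and 3′ UTRs (0.775% against 1.72%) also held fewer, and other exons did not differ (1.11% against 1.17%, Fisher's exact p = 0.748). Promoter summits lay mostly upstream: of the 2630 within 500 bp of a TSS and not on it, 2075 (78.9%) were upstream, against 58.95% of such other regions (odds ratio 2.60, 2.33 to 2.90, Fisher's exact p = 1.05e-71). The median offset was -117 bp for IDR peaks and -37 bp for the other regions.

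**Figure D2:**
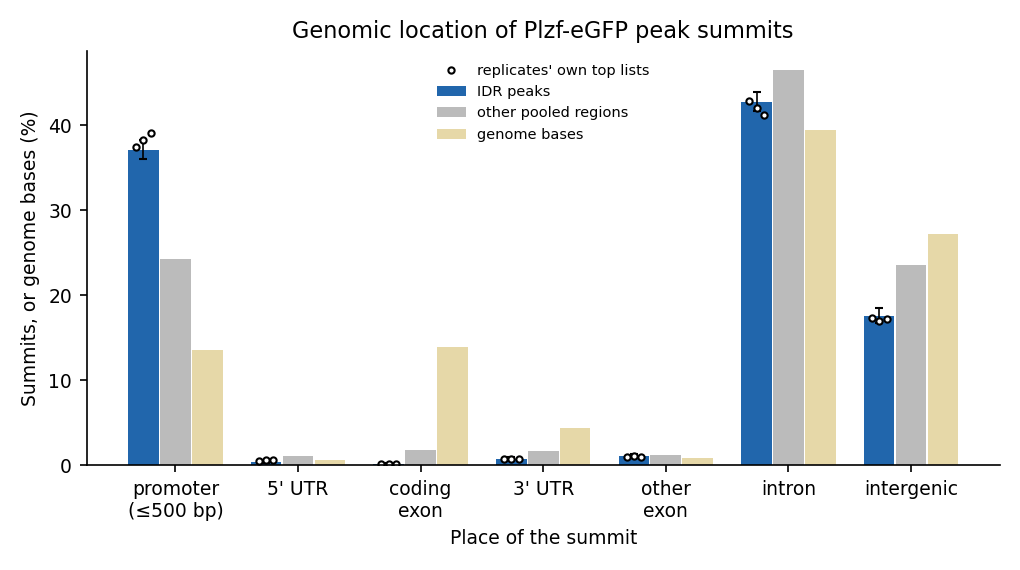
Share of summits, or of genome bases, by place (x axis) in percent (y axis). Blue bars are the 7096 IDR peaks with 95% Wilson intervals, grey bars the other pooled regions, pale bars the genome, and open circles the 3 replicates' own strongest regions. The promoter bar stands at 37.1% for IDR peaks and 24.3% for other regions, and the coding exon bar at 0.183% and 1.77%.

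The strongest promoter peak stood at Ugalt, which encodes a UDP-galactose transporter. It covered X from 2703673 to 2704126 with its summit 43 bp from the TSS and a pooled signal of 2760, and signals of 825, 1166 and 788 in the lists of replicates 1, 2 and 3. The next were CG14100 on 3L (19590391 to 19590846, signal 2494, summit 96 bp from the TSS), PNPase, a polyribonucleotide nucleotidyltransferase, on 3R (31404442 to 31404871, signal 2158, 81 bp), larp, a La-related RNA-binding protein, on 3R (28326308 to 28326864, signal 2098, 335 bp) and Chro, a chromatin protein of polytene interbands, on 3L (22878687 to 22879129, signal 2029, 94 bp). The peak of Hsp27, a small heat shock protein, had a signal of 1927 and lay on 3L from 9383644 to 9384134. That of Gapdh2, a glycolytic enzyme, had a signal of 1611 and lay on X from 15867738 to 15868225. The Polycomb group gene ph-p had a signal of 1559 at an internal TSS (X, 2137025 to 2137617), and Sox14, a transcription factor gene of the ecdysone response, had 1442 (2R, 23978340 to 23978792). The other 16 of the 25 genes were CG18549, CenG1A, CG1888, Tcs5, CG8320, CG9147, CG31145, gish, CG13921, Art3, mRpL41, Fkbp14, Tina-1, Trp1, CG8360 and GstE13, with signals from 1353 to 1972. In 23 of the 25 the summit was within 250 bp of the TSS.

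The single strongest peak of the list was not at a TSS. It lay in an intron of ush, the gene of a GATA cofactor, on 2L from 480564 to 481383, with its summit 1370 bp from the nearest TSS, a pooled signal of 3444 and signals of 946, 1495 and 932 in replicates 1, 2 and 3. The next away from a TSS was a peak in an intron of CG11050 (2L, 6612423 to 6612938, signal 2599). A peak between genes on 2R (13035069 to 13035590, signal 2462) had its nearest TSS, that of CG13323, 11910 bp away. A peak in an intron of Lk6, a protein kinase gene, followed (3R, 11760808 to 11761296, signal 2225). Another peak on 3R (17704186 to 17704664, signal 2087) lay in an exon of lncRNA:CR46035 inside osa. Neither Plzf (2L, 12046711 to 12048918) nor w (X, 2790599 to 2796466) had an IDR peak within 500 bp of a TSS.

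Promoters were more frequent among the strongest peaks. The promoter share was 43.2% (40.9 to 45.5) in the strongest quartile by signal and 34.7%, 35.6% and 35.1% in the following quartiles. The permutation test of the trend gave p = 1e-05, the smallest that 100000 permutations can give. In the replicates' own lists, the strongest quartile exceeded the weakest by 9.70 percentage points in replicate 1 (permutation p = 1e-05) and by 8.51 in replicate 3 (permutation p = 1e-05). In replicate 2 the difference was 2.63 points and did not pass (permutation p = 0.27), so the mean was 6.95 ± 3.79 points (SD, n = 3).

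Cytosolic ribosomal protein genes carried IDR peaks within 500 bp of a TSS more often than other genes. Of the 77 tested, 61 (79.2%) had an IDR peak at a TSS, against 45.8% of the other genes with a pooled region there (odds ratio 4.51, 2.59 to 7.84, Fisher's exact test, adjusted p = 1.53e-07). The strongest were RpL34b (signal 492; 3R, 9401174 to 9401587), RpL32 (480.2; 3R, 30046091 to 30046518), RpL7 (459; 2L, 10200897 to 10201169) and RpS27 (455; 3R, 25247383 to 25247688). RpL10 and RpL12 had only weaker pooled regions. Among the members named, the peaks of RpL7 and RpS27 were found in all 3 replicates, that of RpL32 in 2 and that of RpL34b in 1. With an overlap of 1 bp, or with summits within 100 bp, the peaks of RpL32 and RpL34b were in all 3. Across the genome, 2761 of 13945 protein-coding genes (19.8%) had an IDR peak at a TSS, and 1588 had one held by all 3 replicates.

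Genes of imaginal disc patterning, cuticle and steroid synthesis carried IDR peaks within 500 bp of a TSS less often. Peaks elsewhere were not counted, among them the strongest peak of the whole list, in an intron of ush. In the disc patterning list, 3 of 27 genes (11.1%) had one, against 46.4% of other genes (odds ratio 0.144, 0.0434 to 0.480, Fisher's exact test, adjusted p = 0.00227). These 3 were so (signal 132.0; 2R, 7418882 to 7419321), ush at one of its promoters (110.3; 2L, 490514 to 490953) and C15 (87.1; 3R, 21499525 to 21499964), while B-H1 and Dll had none at a TSS. Of 16 cuticle protein genes only Cpr72Eb had one (signal 349; 3L, 16364243 to 16364547; adjusted p = 0.00844, Fisher's exact test), and Acp65Aa and Cpr12A did not. None of 11 steroid synthesis genes had one, Fdx1 and Fdx2 included (0%, adjusted p = 0.0102, Fisher's exact test). Of 7 alternatives, 2 ended the call for disc patterning, 5 for cuticle proteins and all 7 for steroid synthesis (adjusted p from 0.0588 to 0.329), and none ended that for ribosomal proteins. Where the call ended, disc patterning had an odds ratio of 0.337 with all protein-coding genes as the background, and cuticle proteins 0.179 for the peaks of above-median signal and 0 of 6 genes with a TSS window of 250 bp. Steroid synthesis had 0 of 8 genes with 250 bp, 1 of 11 (odds ratio 0.106) with 1000 bp and 0 of 20 with all protein-coding genes. The alternatives without 1 replicate kept only the IDR peaks held by both others, a smaller set. They gave odds ratios from 0.0804 to 0.301 for disc patterning (0.301 without replicate 3) and from 0.1398 to 0.161 for cuticle proteins, and for steroid synthesis a smaller set could only give 0 of 11 again. The other 28 of the 32 lists tested did not pass, with adjusted p from 0.0606 to 1.

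**Figure D3:**
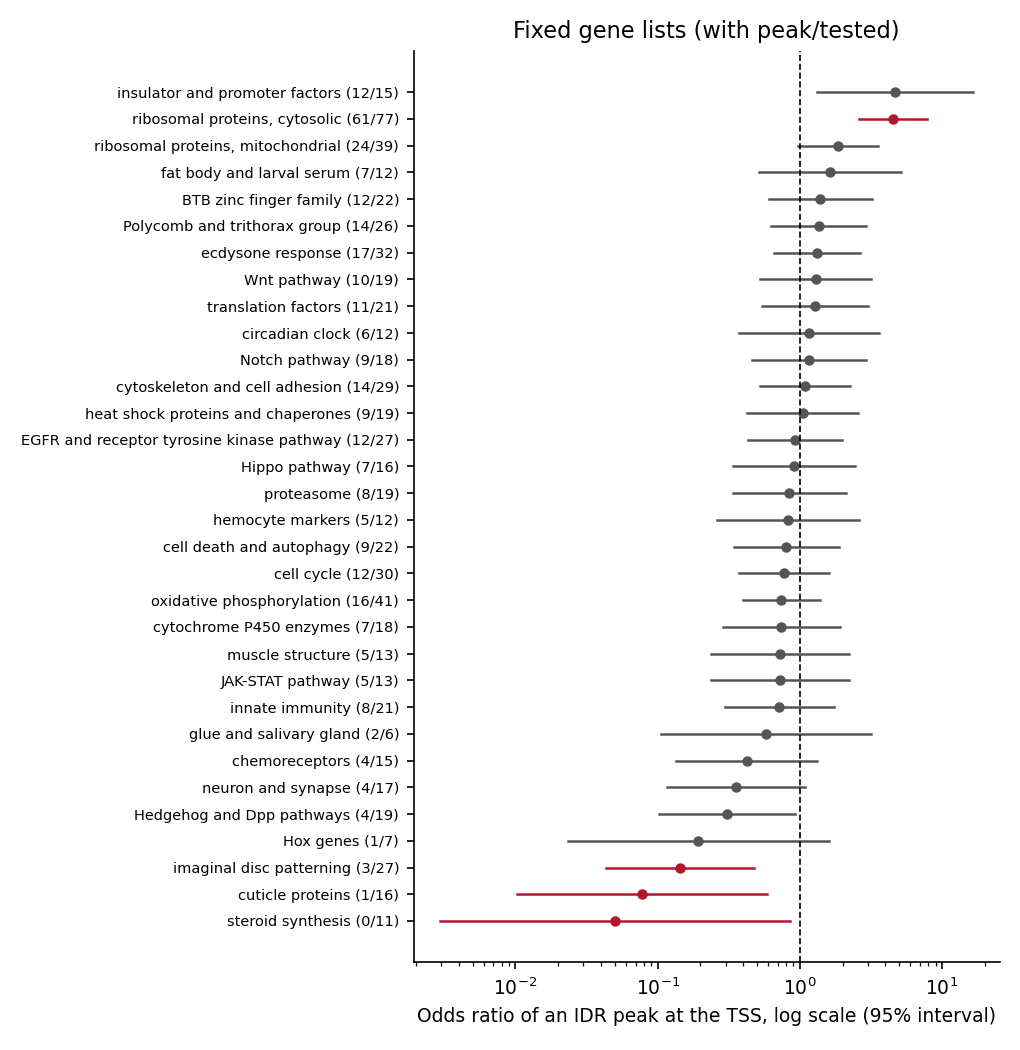
Odds ratio (x axis, log scale, with 95% Woolf intervals) of an IDR peak within 500 bp of a TSS for each of the 32 gene lists tested (y axis, with genes having a peak and genes tested). Lists past an adjusted p of 0.05 are red: cytosolic ribosomal proteins at 4.51, and disc patterning at 0.144, cuticle proteins at 0.0771 and steroid synthesis at 0.0503.

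The X chromosome carried its share of the peaks. It held 1348 IDR peaks (19.0%) against 19.6% of the other pooled regions, an odds ratio of 0.963 (0.8995 to 1.03; Fisher's exact p = 0.283), and 18.9% ± 0.456 (SD, n = 3) of the replicates' own strongest regions. Arms 2L, 2R, 3L and 3R held 1303, 1224, 1541 and 1667 IDR peaks, or 55.4, 48.4, 54.8 and 51.96 per Mb, and X 57.3. Chromosome 4 held 13, or 9.64 per Mb, and the other pooled regions were also sparse there, with 58.6 per Mb against 139.8 to 175.9 on the other arms. In the authors' dm3 list there were 6868 peaks, 96.8% of the dm6 number, with 1301 on X and 13 on chromosome 4.

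Summits of Plzf-eGFP peaks were poor in G and C. The mean GC content within 50 bp of the IDR summits was 33.25% ± 0.106 (SE over 7096 peaks), against 45.1% ± 0.0827 in windows 300 bp away and 42.15% for the arms. The other pooled regions had 39.8% at the summit and 42.97% at the same distance. The replicates' own strongest regions had 33.8% ± 0.511 at the summit (SD, n = 3). The summit value was 30.7% in the strongest quartile by signal, then 32.4%, 33.98% and 35.9%. The fall from flank to summit was 9.75 percentage points ± 0.259 (SE) for promoter peaks and 13.5 ± 0.185 for the 3735 peaks over 1000 bp from a TSS.

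**Figure D4:**
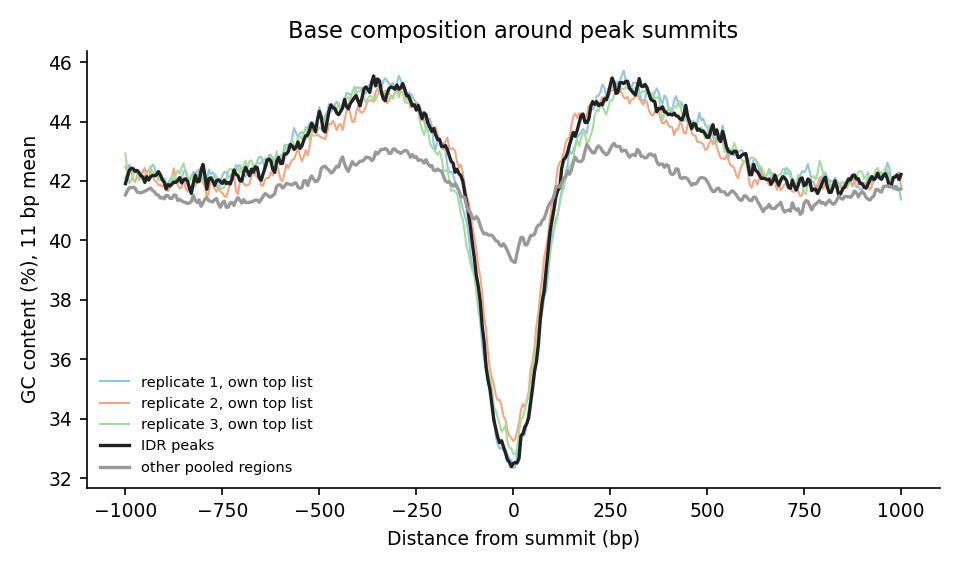
GC content in percent (y axis, mean over 11 bp) by distance from the summit in bp (x axis) for the IDR peaks (black), the other pooled regions (grey) and the 7096 strongest regions of each replicate (colours). All 3 replicates and the IDR peaks fall to between 32.3% and 33.3% at the summit, and the other regions to 39.3%.

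Motifs rich in A and T were more frequent at summits than in the flanks. Most of these differences were absent against GC-matched summits of other pooled regions. That control changed both the base composition and the kind of region compared. No motif was tested against windows outside the pooled list, so the loss cannot be assigned to base composition alone. GATA sites (WGATAR) were in 22.7% of summit windows and 14.5% of flanks (adjusted p = 7.35e-37, McNemar's exact test), TATA boxes in 9.58% and 4.54%, and the homeodomain core TAATTA in 9.78% and 5.27%. Against GC-matched summits of other pooled regions, the matched shares were 22.8% for GATA, 10.6% for TATA and 10.5% for the homeodomain core, with Fisher's exact adjusted p of 1, 0.169 and 0.519. Of 30 motifs, 21 differed from the flank at higher coordinates, the only one tested, and 5 kept their direction and passed with matched composition. These were the DNA replication-related element (DRE; 0.944% against 0.521% matched), the BEAF-32 box, whose core is part of the DRE (12.54% against 11.01%), core promoter motif 7 (1.55% against 0.803%), the partial CTCF site (0.8315% against 0.423%) and the CA repeat, which was lower (1.23% against 1.83%). Their adjusted p values were 0.0245 for all but motif 7, which had 0.000678 (Fisher's exact test). Against the flanks, the 4 higher motifs did not pass among the peaks of above-median signal (McNemar's exact test: DRE log2 ratio 0.66, adjusted p = 0.418; BEAF-32 box 0.06, 0.557; motif 7 0.60, 0.449; CTCF 0.04, 0.701). Over all peaks these ratios were 1.2 for DRE, 0.21 for the BEAF-32 box, 0.76 for motif 7 and 0.70 for CTCF. The tested flank held 0.409% for CTCF and 0.324% for DRE. The untested flank held 0.606% and 0.479%, nearer to the summit shares. For the BEAF-32 box (10.8% and 10.9%) and motif 7 (0.902% and 0.916%) the flanks differed little. Outside promoters the 4 motifs did not pass either (log2 ratios 0.36, 0.07, 0.37 and 0.18, McNemar's exact test, adjusted p from 0.396 to 0.497). In promoter peaks all 4 passed, with log2 ratios of 1.35, 0.38, 1.00 and 1.43. The CA repeat passed in all 3 sets. Poly A tracts were higher than in the flanks (9.09% against 6.27%) and lower than in GC-matched regions (12.4%, adjusted p = 7.45e-09, Fisher's exact test). GAGA sites were in 10.5% of summits and 16.3% of flanks, and 9.67% of the GC-matched regions (adjusted p = 0.353, Fisher's exact test). In the search of all 7-mers, of 8192, 1667 were higher and 3262 lower at summits than in flanks, led by TAATATA (7.91% against 1.75%) and TCTTAAA (5.61% against 1.26%). Against GC-matched pooled regions 1 was higher and 5 lower. Against GC-matched genome windows outside the pooled list 138 were higher and 73 lower, and 43 were at least 2-fold higher in both sets of alternating peaks. Both of these controls were added for 7-mers after seeing the data.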

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

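Both results here concern regions outside the chromosome arms that the comparisons used. In replicate 2, 6 regions of the dm6 list lay on the mitochondrial genome and the dm6 lists of replicates 1 and 3 and the pooled list held 0. The strongest of the 6 covered positions 1681 to 2071 with a signal of 768, rank 19 of the 30000 regions of that replicate. Among the IDR peaks on dm3, 5 lay on sequences outside the major arms, 3 on Uextra and 2 on XHet, with signals from 80.4 to 125.4. No explanation was tested for either. With 3 samples in the group, no replicate was tested as an outlier.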

How the results depend on the processing

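No paired analysis was possible because the series has 1 group. The 7-mer controls matched on GC content were chosen after seeing the data. The promoter odds ratio, the X odds ratio and the trend of promoter share with signal over all peaks kept their direction and their side of the threshold under each alternative run. The share of peaks in all replicates moved from 52.9% to 71.8% with a 1 bp overlap, 62.4% with summits within 100 bp, 65.9% for the peaks of above-median signal, 79.9% when all regions per replicate were searched, and 61.0% to 61.8% without 1 replicate, where fewer replicates are required. The mean pairwise overlap moved from 71.1% to 80.5% with 1 bp and 77.5% for the top 500, and was 68.0% to 76.7% without 1 replicate, the highest without replicate 2. With all protein-coding genes as the background, 7 lists were higher instead of 1, and 4 were lower instead of 3. Chemoreceptors (odds ratio 0.0704, adjusted p = 6.97e-16) and cytochrome P450 enzymes (0.382, adjusted p = 0.0371) were among the lower ones (Fisher's exact test). Neuron and synapse genes passed as lower with a TSS window of 250 bp (0.0940, adjusted p = 0.0327, Fisher's exact test). The number of lower lists fell from 3 to 1 for the peaks of above-median signal and to between 0 and 1 without 1 replicate, where the peaks were also limited to those held by both others, so the effects of the replicate and of the smaller set are not separated. Motifs higher at summits numbered 11, and 7 within 25 bp, 4 against GC-matched regions, 5 for peaks outside promoters and 6 for the peaks of above-median signal. Without 1 replicate, 7 to 9 motifs were higher. These had to pass in the own strongest regions of both other replicates, so this count is not on the IDR peaks. Motifs lower numbered 10, and 2 against GC-matched regions. Higher k-mers numbered 599 at length 6, 3027 at length 8, 1 against GC-matched regions and 138 against GC-matched unlisted windows, and lower ones 1100 at length 6, 5 and 73 against the same controls. Of the directions that turned, only that of poly A passed the threshold under the alternative. Odds ratios turned with a TSS window of 250 bp for ecdysone response (0.777) and cytoskeleton (0.543), the latter also for the peaks of above-median signal (0.558) and without 1 replicate (0.630 to 0.741). Without 1 replicate, with the same limit, the ranges were 0.874 to 1.38 for BTB zinc fingers and 0.809 to 1.17 for cytochrome P450 enzymes. Against GC-matched regions, log2 ratios turned for GAGA (0.12), motif 6 (-0.39), TATA (-0.15), GATA (-0.01), homeodomain (-0.10), Su(Hw) (-0.30) and poly A (-0.45), and in promoter peaks for STAT (-0.28). The cause was not tested. The matched control holds base composition equal but also replaces the flanks with other pooled regions, which may hold the same sites. The effects of these changes are not separated. The depth of the libraries is unknown and its effect could not be measured.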

Other observations

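The tests of general GC bias and of other housekeeping genes, and both GC-matched 7-mer controls, were chosen after the results they bear on had been seen, and the genes in the next paragraph were chosen after their values were seen.

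Only IDR peaks within 500 bp of a TSS were counted for the genes in this paragraph. Among the 32 ecdysone response genes with a pooled region at a TSS, 17 (53.1%) had an IDR peak there, which did not differ from other genes (odds ratio 1.32, 0.657 to 2.65, Fisher's exact test, adjusted p = 0.971). Those with one included Eip75B (signal 574), Hr3 (294), Eip74EF (227), usp (203), br (118) and EcR (116), while ftz-f1, Blimp-1 and Kr-h1 had none. With all protein-coding genes as the background the odds ratio for the ecdysone genes was 3.64 (adjusted p = 0.00124, Fisher's exact test), and 32 of the 36 had a pooled region at a TSS against 5969 of all 13945. Of 15 insulator and promoter factor genes 12 had an IDR peak (odds ratio 4.66, 1.31 to 16.5, adjusted p = 0.0606, Fisher's exact test; odds ratio 2.045 to 4.225 for the peaks held by both other replicates, lowest without replicate 1), among them Chro (2029), Cp190 (668), Trl (396), M1BP (335), Dref (197) and BEAF-32 (121), while CTCF and pita had none. Of 19 heat shock and chaperone genes 9 had one, with Hsp27 (1927), Hsp26 (631), Hsp83 (437) and Hsp22 (222) ahead, and this did not differ from other genes (adjusted p = 1, Fisher's exact test). Among genes that are not protein-coding, 21 of the 139 tRNA genes and 6 of the 14 snRNA genes with a pooled region at a TSS had an IDR peak there, out of 290 and 32 annotated, and none of the 99 rRNA genes had a pooled region. The aligner and its treatment of reads that match several places are not known. The lack of rRNA regions is therefore not read as a lack of binding.

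For the summits rich in A and T, AT-rich core promoters are argued against by peaks over 1000 bp from a TSS, whose fall in GC was 138% of that at promoters. A bias of the libraries towards AT-rich fragments and a property of the sites bound cannot be told apart, because the IDR peaks exceeded other pooled regions in A and T over 200 bp around the summit (35.3% against 40.2% GC), 400 bp (38.95% against 41.1%) and 600 bp (40.9% against 41.7%), with a difference of -0.103 points ± 0.0602 (SE) over 800 bp, and the fragment lengths within the labelled range are unknown. Against GC-matched pooled regions 1 7-mer (CGCCATC, 0.987% against 0.381%) was at least 2-fold higher in both sets of alternating peaks, fewer than the 10 set beforehand. DRE, the BEAF-32 box, motif 7 and CTCF also passed, so a preference limited to a few words is not excluded. The match did not include promoter share, which was 37.1% for IDR peaks and 24.3% for all other pooled regions. Its part in these motif differences was not tested. Against GC-matched genome windows 1000 bp or more from every pooled region there were 43 such 7-mers, led in significance by CAGTGCA (3.24% against 0.916%). The 43 words may be common to strong and weak regions of the pooled list, so a candidate explanation is a feature that all listed regions share, and no biological explanation was tested, since neither a control library nor an untagged line was analysed here.

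The ribosomal proteins were the only list past the threshold with a higher share of IDR peaks. Translation factor, oxidative phosphorylation and proteasome genes, joined after their values were seen, had an odds ratio of 0.883 (0.567 to 1.37). Its upper limit lay below the lower limit of 2.59 for ribosomal proteins. Because the lists were joined with their values known, this describes these genes only. It cannot decide on a preference for housekeeping genes in general. The mitochondrial ribosomal proteins, not in that joint set, had 1.87 (0.977 to 3.57; 24 of 39 genes, Fisher's exact test, adjusted p = 0.343) and 2.23 to 2.31 for the peaks held by both other replicates, so a preference shared by some housekeeping genes may remain. Base composition is argued against by a logistic model with summit GC content, in which the odds ratio of the ribosomal protein genes was 9.28 (5.24 to 16.5, Wald interval). Summit GC was that of the strongest pooled region at a TSS of each gene, IDR peak or not, and entered as a linear term. Its mean was 44.7% for the ribosomal protein genes against 37.5% for other genes. Expression was not measured in these files, so an effect limited to the most highly transcribed genes may remain, and no biological explanation was tested.

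The neighbourhood of Plzf was examined for extra signal, since the line carries a tagged copy of the gene. Within 20 kb of Plzf there were 18 pooled regions and 5 IDR peaks, whereas w had 11 pooled regions. The count of pooled regions at Plzf, not scaled by gene length, exceeded that of 82.6% of protein-coding genes. Their density exceeded that of 88.1%. The strongest of them, with a signal of 535.0, lay between CG6770 and Plzf (2L, 12046040 to 12046452). The count fell between the limits set beforehand, so extra copies of the locus and ordinary variation between genes cannot be told apart here, and no biological explanation was tested. A count of called regions is also not a measure of copy number.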
